A study of Homo sapiens with 8 samples.

How the data were processed

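The data came from single-cell RNA libraries of fixed cells, made with a probe-based chemistry (10x Genomics Flex, Human Transcriptome Probe Set v1.0.1, per the labels' protocols), in which paired probes are ligated on each transcript and counted with molecular identifiers (UMIs). Each of the 8 libraries held A375 melanoma cells together with human monocyte-derived macrophages, with or without monocyte-derived dendritic cells. The authors deposited 1 matrix of raw UMI counts per library and a feature list, the same in all libraries, that pairs gene identifiers with symbols. Per the submitters' processing notes, the matrices were made with Cell Ranger 8.0.1 against GRCh38. The deposited count matrices list nearly every barcode with a UMI, before any calling of cells, and carry no normalization. Cells of several donors were pooled in each matrix without a map of cells to donors, so each library was treated as 1 sample and no donor was analysed apart.

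All further steps were computed from these counts with Python 3.11.15 (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scipy 1.17.1) and R 4.3.3 (edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0). Of 34114 features, 542 rows for withdrawn probes (1.232% of UMIs) and 131 rows of XIST, TSIX and the Y chromosome were left out, and 33441 genes remained. Barcodes with at least 1000 UMIs, at least 500 genes detected and at most 15% mitochondrial UMIs were kept as cells. The 88939 cells kept were clustered together, without integration, by the Leiden method (resolution 1) on 30 principal components of 2000 variable genes with 15 neighbours, which gave 40 clusters. Scrublet was run on each library to score doublets. Its automatic threshold marked almost no cells, so cells with a score above 0.2 were left out of the classes, a limit set after the data were seen.

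Clusters were named from fixed sets of 20 markers each for melanoma, macrophage and dendritic cells. A cluster was called melanoma-like when at least 8 melanoma markers stood over 1.5 times their level in the other cells, at most 1 macrophage marker did so, and macrophage markers summed to no more than 3000 CPM, the counts scaled to a common library total. It was called dendritic-cell-like when at least 10 dendritic cell markers stood over 1.5 times their level in the other cells. It was called macrophage-like when at least 10 macrophage markers reached 20 CPM and no melanoma or dendritic cell marker was among its 10 leading genes. These numbers were set after the clusters were seen. Clusters of fewer than 50 cells, of low UMI count or of high doublet score stayed unnamed. So did clusters with melanoma markers together with macrophage markers, and clusters that met none of the conditions for a name. In all, 77088 cells were named. Names end in "-like" because they rest on markers alone.

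Counts were summed over the cells of each class in each library. Genes were tested with edgeR's quasi-likelihood F-test after TMM normalization and edgeR's filter on low counts, with Benjamini-Hochberg adjustment and a threshold of 0.05. The model held culture type, A375 state and drug as additive terms, so that each level of a factor was held by 4 libraries matched on the other factors, with 4 residual degrees of freedom. The residual holds the interactions and the spread between libraries, not the spread between donors, and no pair of single conditions was tested. Interaction terms were tested in models with 3 residual degrees of freedom. Dendritic-cell-like cells were compared over the 4 tri-culture libraries, 2 against 2, with 1 residual degree of freedom. The drug was also compared within each A375 state, 2 libraries against 2, in 1 model over all 8 libraries in which A375 state was crossed with culture and with drug, with 2 residual degrees of freedom. The interaction of A375 state with culture was tested as well. These 3 comparisons were added after the data were seen, while the other 10, their tests of genes, the gene lists, the marker sets and the rule for named genes were fixed before the data were examined. List tests were planned for the additive comparisons, those of dendritic-cell-like cells included. The list tests of the interactions and of the added comparisons were not planned. Log2 changes are edgeR's estimates and are given with a standard error derived from the test statistic. CPM values are means over libraries.

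The rule for named genes took the 12 largest rises and the 12 largest falls past the threshold (6 and 6 for interactions and dendritic-cell-like cells). A named gene had the same direction in every matched pair of libraries and a mean of at least 20 CPM at its higher level. For interactions, which have no pairs, 1 library of at least 20 CPM was enough. In macrophage-like and dendritic-cell-like cells, genes whose mean CPM in melanoma-like cells was over 2 times that in the class were left out of the rule, and in melanoma-like cells the reverse with macrophage-like cells. No limit was set for macrophage RNA in dendritic-cell-like cells. AXL, MERTK, TYRO3, GAS6 and PROS1 were named in every class, DUSP6, SPRY2 and SPRY4 in melanoma-like cells, and members of the gene lists could be named as examples. Members over the limit of 2 are said to be more abundant in the other cell class. Genes were placed on GRCh38 with the GENCODE annotation. Probe counts carry no strand ambiguity, but near-identical gene copies can share a probe, so members of such families are uncertain.

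Of the 32 gene lists, 27 to 30 per comparison were tested with camera (limma) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, and again with an estimated correlation. P values were adjusted over the lists within each comparison. A further planned list test, fry (limma), asks whether the members changed at all, not whether they changed more than other genes. Its values are given for bemcentinib against DMSO over all contexts of a class. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. Within each of the 4 contexts (a culture type with an A375 state), bemcentinib and DMSO were compared as a log2 ratio of summed counts, which is 1 library against 1 and has no test. A list's median ratio was placed among 10000 random lists of equal size drawn from 20 bins of mean expression, and its interval came from 2000 bootstrap draws of its members. Shares of cells have exact (Clopper-Pearson) 95% binomial intervals and were compared by exact two-sided permutation of signs over matched pairs. Floors for genes without counts are 3 counts over the group. The binomial and Poisson intervals and the floors cover counting error only. The bootstrap intervals cover the spread among list members, drawn as if independent.

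The libraries held 94365926 to 107037955 UMIs each, and the median UMIs per kept cell ran from 5553 to 10406. The tests were run first on simulated counts with the real means and library sizes, in which 200 genes were changed. For bemcentinib against DMSO in macrophage-like cells, 0.5% of genes changed 1.5-fold, 73.5% of those changed 2-fold and 92% of those changed 4-fold were recovered, among 12760 to 12773 genes. For the same comparison in melanoma-like cells these shares were 46%, 79.5% and 96%, among 13471 to 13497 genes. Wrong calls numbered 0, 12 and 15 in the former and 3, 12 and 13 in the latter. For bemcentinib beside untreated A375 there were 26, 18 and 15 wrong calls beside 92, 146 and 187 right ones, and for bemcentinib in dendritic-cell-like cells 9, 38 and 30 beside 85, 182 and 199. For the interaction of bemcentinib with A375 state there were 3, 16 and 14 beside 11, 137 and 183, and for that of A375 state with culture 9, 18 and 15 beside 78, 167 and 187. For interactions the fold was set between the 4 libraries on either side of the term. On the scale of the reported log2 interactions the simulated change was thus 2 times the log2 of the fold. Smaller interactions were not simulated. The share of wrong calls among all calls was over 0.05 in most of these settings. Bemcentinib beside injured A375 and A375 state in dendritic-cell-like cells were not simulated. Alternatives tried were DESeq2's size factors, no filter on low counts, DESeq2's Wald test, at least 1000 genes per cell, doublets kept, no covariates, all myeloid cells together, leaving out each library in turn, other prior counts, and, chosen after the data were seen, added interaction terms and the removal of single clusters.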

Results

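Mixed cultures were profiled to ask how inhibition of AXL, a receptor tyrosine kinase of the TAM family, changes myeloid cells beside melanoma, and whether earlier targeted therapy of the tumour cells and the cell mix alter that change. A375, a human melanoma line, was either left untreated or injured with trametinib, a MEK inhibitor, and dabrafenib, a BRAF inhibitor. It was then cultured with human monocyte-derived macrophages (co-culture), and in part of the wells monocyte-derived dendritic cells of the same donors were added after 24 h (tri-culture). Cultures received bemcentinib, an AXL inhibitor, or its solvent DMSO. The 8 conditions crossed these 3 factors with 1 library each, so no condition had a replicate. Co-cultures were harvested at 24 h from 6 wells per donor and tri-cultures at 48 h from 3 wells per donor, so culture type stands for time and wells as well as for dendritic cells.

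The libraries had similar totals of UMIs, while the median UMIs per kept cell ran from 5553 in the untreated co-culture with DMSO to 10406 in the injured tri-culture with DMSO. With untreated A375, the co-cultures held 99388336 UMIs (DMSO) and 103105826 (bemcentinib), and the tri-cultures 99471023 and 100934123. With injured A375, the co-cultures held 107037955 and 94365926 UMIs and the tri-cultures 94486320 and 95485759. Between 7253 (tri-culture, injured, DMSO) and 12909 cells (co-culture, untreated, DMSO) were kept per library. Clusters of low UMI count, left unnamed, made up 33.74% and 24.27% of the kept cells in the untreated tri-cultures with DMSO and bemcentinib, and 0.61% to 6.8% elsewhere.

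Among named cells, macrophage-like cells were the most frequent class in every library, and melanoma-like cells had a lower share with injured A375 and in tri-culture. Dendritic cells were added to the tri-cultures only, which by itself lowers the shares of the other classes there. Melanoma-like cells formed 18.62% of named cells on average with untreated and 10.25% with injured A375, a difference of -8.37 ± 2.84 percentage points (SD over 4 matched pairs) that was negative in 4 of 4 pairs. In single libraries their share ran from 6.95% (95% interval 6.36 to 7.57) in the injured tri-culture with DMSO to 23.83% (23.06 to 24.6) in the untreated co-culture with DMSO. Dendritic-cell-like cells formed 26.19% to 31.1% of the tri-cultures and at most 0.05% of the co-cultures. Bemcentinib went with a change of 0.41 ± 2.26 points for melanoma-like cells, higher in 2 of 4 pairs (exact two-sided permutation p = 0.875), and of 0.69 ± 2.91 points for macrophage-like cells (exact p = 0.625). The differences by A375 state and by culture reached the smallest p that 4 pairs allow, 0.13 in the exact permutation test, so no share could pass a threshold of 0.05. Seeding and harvest set these shares too. An unnamed cluster of low UMI count (2831 cells), led by VGF, PLK1 and ETV4 and with 9 melanoma, 3 macrophage and 5 dendritic cell markers above the rest, came to 51% and 47.9% from the untreated tri-cultures with DMSO and bemcentinib. Another of low UMI count (2331 cells) had 11 dendritic cell markers above the rest. It came to 51.8% and 30.1% from the untreated tri-cultures with DMSO and bemcentinib, and to 0.2% and 17.7% from the injured ones. No share was computed with either cluster, so the directions by culture, and the dendritic shares, hold for named cells only.

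**Figure D1:**
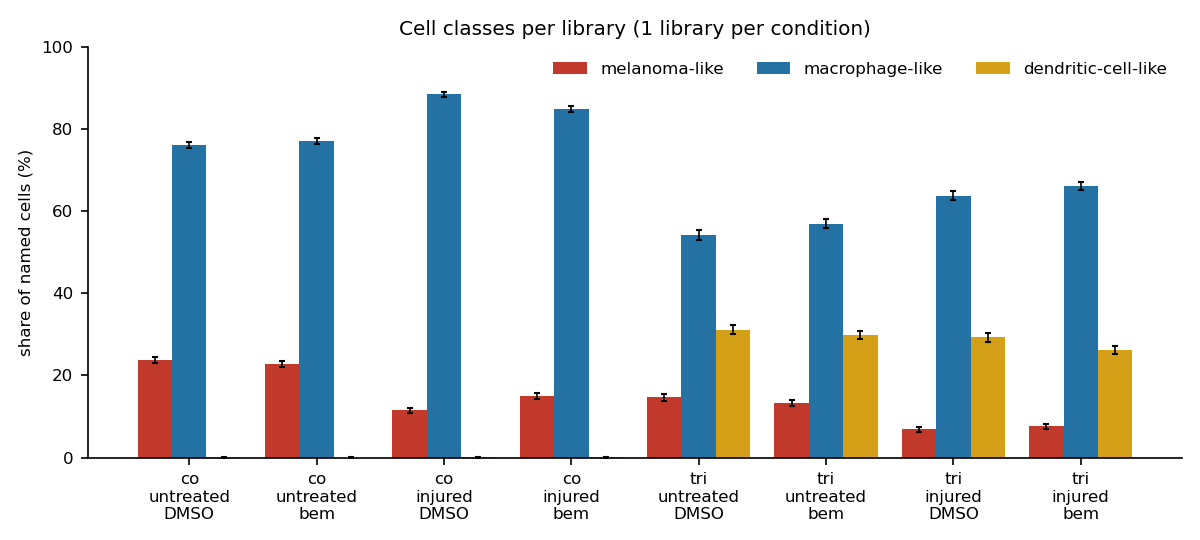
Share of named cells in percent (y axis) per class in each of the 8 libraries (x axis, bem for bemcentinib), with exact 95% binomial intervals as error bars. Melanoma-like cells ran from 6.95% to 23.83%, and dendritic-cell-like cells were at least 26.19% in the tri-cultures.

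Injury left a deep mark on the melanoma-like cells: the output of the inhibited MAPK pathway and the cell cycle were lower, and AXL itself fell. Of 19 measured genes of MAPK pathway output, 17 fell and none rose (17 fell and 1 rose adjusted over the list alone), with a median log2 change of -2.01. SPRY4, a feedback inhibitor of the pathway, fell by 5.11 ± 0.15 on the log2 scale (307 to 8.78 CPM), DUSP6, an ERK phosphatase, by 2.45 ± 0.15 (492 to 87.1 CPM), and SPRY2 by 1.51 ± 0.07 (463 to 163 CPM). ETV4, a transcription factor downstream of ERK, fell by 5.25 ± 0.32 and the cyclin CCND1 by 2.82 ± 0.28. All 20 genes of the S phase list fell (median -1.64), among them the replication helicase subunit MCM2 (-1.47 ± 0.21), and 19 of 20 genes of the G2 and M phase list (median -2.15), among them TOP2A (-2.28 ± 0.60) and MKI67 (-2.70 ± 0.74). AXL dropped from 240 to 91.7 CPM, a log2 change of -1.40 ± 0.10 (adjusted p = 3.36e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), while TYRO3 rose by 0.83 ± 0.10 and the TAM ligand PROS1 by 1.77 ± 0.15.

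Genes of the integrated stress response and p53 lists fell with injury as well, and genes of MHC class I presentation rose. In the amino acid and integrated stress response list 15 of 16 genes fell and 1 rose (median -0.81), such as ATF4 (-0.62 ± 0.08) and TRIB3 (-1.51 ± 0.10). Of 16 p53 targets 11 fell, including CDKN1A (-1.86 ± 0.19). Of 11 genes of MHC class I presentation that were measured, 9 rose and none fell (median 0.86), such as the immunoproteasome subunit PSMB9 (0.80 ± 0.12) and the peptide transporter TAP1 (0.39 ± 0.11), and CIITA, the master regulator of MHC class II, rose by 3.05 ± 0.15. NGFR, a neural crest receptor in the dedifferentiation list, rose by 3.89 ± 0.33. The largest rises by the rule included the homeobox gene DLX5 (8.80 ± 0.36, 7 against 1513 counts), OLFML2A (7.03 ± 0.47) and IGFBP5, an IGF-binding protein (6.10 ± 0.50). The largest falls included the EGF receptor ligand AREG (-9.59 ± 0.53, 119 to 0.142 CPM), CEMIP (-7.38 ± 0.25) and the collagenase MMP1 (-6.55 ± 0.83).

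In all, 4100 genes rose and 4375 fell in melanoma-like cells with injury, of 13594 tested over 4 libraries against 4 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The cells also lay in different clusters by A375 state: cluster 10 held 88.11% to 99.54% of the melanoma-like cells of the injured libraries and at most 0.1% in the untreated ones. By camera the MAPK list had adjusted p = 1.72e-06, and adjusted p = 0.117 with an estimated correlation. The adjusted p values of the S phase, G2 and M phase, stress response, MHC class I and p53 lists were 3.70e-05, 4.65e-04, 1.50e-04, 0.00167 and 8.58e-04. They were, in that order, adjusted p = 0.593, 0.663, 0.462, 0.538 and 0.538 with an estimated correlation.

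**Figure D2:**
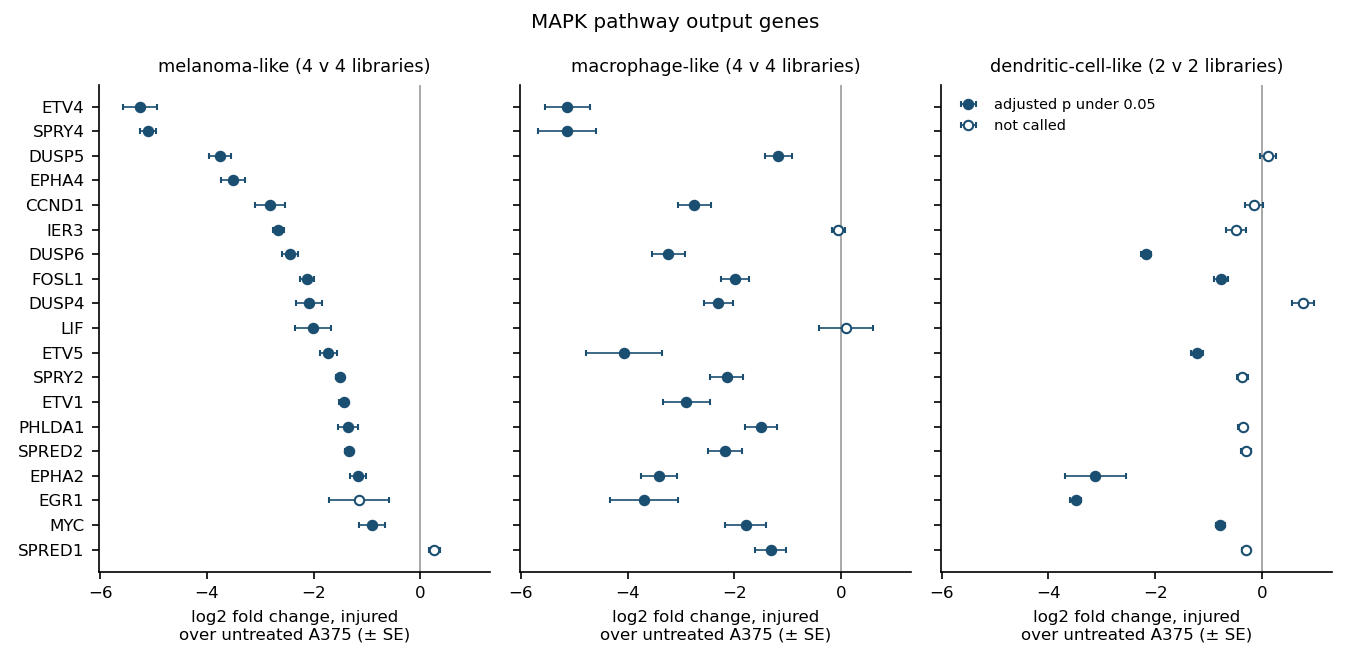
Log2 change with injured over untreated A375 (x axis, edgeR estimate with standard error) of genes of MAPK pathway output in the 3 classes, over 4, 4 and 2 libraries per level, with filled points for an adjusted p under 0.05. Most members lie below 0 in all 3 panels, and genes without counts at a level are left out.

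Macrophage-like cells beside injured A375 had lower MAPK output and inflammatory genes, lower cholesterol synthesis genes, and higher lysosomal genes than those beside untreated A375. Of 18 MAPK output genes measured, 16 fell and none rose (16 adjusted over the list alone), with a median log2 change of -2.24; ETV5, an ERK-induced transcription factor, fell by 4.07 ± 0.71 (110 to 9.15 CPM) and DUSP6 by 3.24 ± 0.31 (160 to 18.1 CPM). DUSP6 and 13 other members are more abundant in melanoma-like cells, and A375 RNA made up at most 0.0262% to 0.174% of the macrophage-like counts in any library. Of 24 inflammatory cytokines and NF-kB targets, 11 fell and none rose (13 fell and 1 rose adjusted over the list alone). They included the cytokines IL1B (-4.63 ± 0.18, 147 to 5.52 CPM) and TNF (-1.86 ± 0.21), and the monocyte chemoattractants CCL2 (-4.27 ± 0.66, 1240 to 75.7 CPM) and CCL7 (-4.55 ± 0.72). In the cholesterol list 5 of 23 fell (21 adjusted over the list alone; median -0.76), among them HMGCS1, an early enzyme of the pathway (-0.80 ± 0.17). In the unfolded protein response list 8 of 14 fell and 1 rose, such as the chaperone HSPA5 (-0.75 ± 0.13).

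Lysosomal and complement genes went the other way in part. In the lysosome and TFEB target list 9 of 33 rose and none fell (15 rose adjusted over the list alone; median 0.32), among them GPNMB, a lysosomal glycoprotein (0.93 ± 0.14, 3180 to 5950 CPM), and the protease CTSD (0.88 ± 0.14). In the complement list 6 of 14 rose and 1 fell, such as C3 (1.25 ± 0.12) and CFB (2.31 ± 0.36). The type I interferon list had no member past the threshold in 26 (median -0.26), and of 14 interferon gamma chemokines and effectors 2 rose and 1 fell (3 and 1 adjusted over the list alone; median 0.13). By the rule, the largest rises included the chemokine receptor CCR7 (6.60 ± 0.92, 0.295 to 31.6 CPM), the tryptophan-degrading enzyme IDO1 (5.29 ± 0.67, 2.95 to 125 CPM), the T cell chemoattractants CXCL9 (4.73 ± 0.36) and CCL5 (3.02 ± 0.23, 70.9 to 634 CPM), and PTGES, a prostaglandin E synthase (3.91 ± 0.53). IDO1 stood at 334 and 165 CPM in the injured co-cultures with DMSO and bemcentinib. In the injured tri-cultures it stood at 0.309 and 0.344 CPM, and CCR7 averaged 0.35 CPM over the tri-cultures. The means of these genes over both cultures thus rest on the co-cultures. The largest falls included the receptors CLEC5A (-6.16 ± 0.77), FCAR, an IgA receptor (-2.93 ± 0.09), and VSIG4, a complement receptor (-2.58 ± 0.16). MERTK, the TAM receptor of resting macrophages, fell from 80.4 to 44.6 CPM (-0.85 ± 0.11), and AXL (0.47 ± 0.37) did not pass.

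With injured A375, 592 genes rose and 675 fell in macrophage-like cells, of 12854 tested (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4 libraries against 4). By camera the adjusted p was 7.11e-11 for MAPK output, 6.67e-05 for NF-kB targets, 0.00198 for the unfolded protein response, 1.25e-07 for cholesterol and 9.92e-06 for lysosomes, and each of these had adjusted p = 0.443 with an estimated correlation. Complement had 0.17, interferon gamma 0.193 and type I interferon 0.483. Without the untreated co-culture with bemcentinib 41 genes were called, and without covariates 22. The change with A375 state differed between the cultures for 136 genes, a test added after the data were seen, and for 0 without either injured co-culture. The comparison sets cells of different clusters against each other. In co-culture, clusters 2, 4 and 6 each held at most 0.11% of the macrophage-like cells of a library beside injured A375, and clusters 0, 3 and 8 at most 0.69% beside untreated A375.

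Macrophage-like cells of the tri-cultures had lower interferon, NF-kB and metallothionein genes and higher genes of alternative activation than those of the co-cultures. Of 26 type I interferon genes 25 fell and none rose (26 fell adjusted over the list alone; median -2.07), such as MX1 (-2.52 ± 0.40, 540 to 96.9 CPM) and IFIT1 (-2.20 ± 0.54), both antiviral effectors, and ISG15 (-2.71 ± 0.52). Of 14 interferon gamma chemokines and effectors 10 fell and 1 rose, with IDO1 (-9.25 ± 0.75, 128 to 0.196 CPM) and CXCL10 (-5.74 ± 0.78, 515 to 13.3 CPM) among the largest falls by the rule. Of 24 NF-kB targets 18 fell and none rose, such as the neutrophil chemoattractant CXCL8 (-4.46 ± 0.34, 783 to 40.1 CPM) and TNFAIP6 (-6.22 ± 0.53). Of 7 metallothioneins 5 fell, and of 16 dendritic cell maturation genes 10 fell and 1 rose.

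In the alternative activation and immunoregulation list 13 of 18 rose and 3 fell (the same counts adjusted over the list alone; median 1.46). Members that rose included F13A1, a clotting factor subunit (6.53 ± 0.69, 35.9 to 2740 CPM), the chemokines CCL18 (3.34 ± 0.34), CCL17 (5.87 ± 1.45) and CCL13 (4.74 ± 1.08), the folate receptor FOLR2 (1.28 ± 0.23) and the scavenger receptor CD163 (0.92 ± 0.20). Other large rises were ALOX15, a lipoxygenase (8.04 ± 0.34), the IgE receptor subunit FCER1A (7.23 ± 0.41), WNT5B (0.269 to 34 CPM) and the inhibitory receptor CD200R1 (4.46 ± 0.64). Dendritic cell RNA, which the tri-cultures alone contain, amounted to at most 5.33%, 2.25%, 0.715% and 1.16% of the macrophage-like counts in the 4 tri-cultures. These bounds came from the fixed marker with the lowest ratio of its level in macrophage-like to that in dendritic-cell-like cells. They hold for RNA like that of the average dendritic-cell-like cell. The median marker ratio was 26.0% and 10.2% in the untreated tri-cultures with DMSO and bemcentinib, and 4.14% and 4.51% in the injured ones. At the bounds, dendritic cell RNA could give at most 60.8% of the tri-culture level of ALOX15 and 73.3% of that of FCER1A. FCER1A itself set the bound in the untreated tri-culture with DMSO and the injured one with bemcentinib, so its share tests nothing there. For CCL17 the share was 17.7%, for CCL13 11.6%, for WNT5B 4.55% and for F13A1 4.28%. GAS6, the TAM ligand, rose from 24.8 to 130 CPM (2.44 ± 0.24), AXL fell from 29.1 to 5.88 CPM (-2.24 ± 0.38) and is more abundant in melanoma-like cells, and MERTK (-0.05) did not pass.

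Between the cultures 2210 genes rose and 2284 fell in macrophage-like cells, of 12854 tested (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4 libraries against 4). By camera the type I interferon list had adjusted p = 2.88e-08 (adjusted p = 0.593 with an estimated correlation) and the NF-kB list 2.49e-07 (adjusted p = 0.483 with an estimated correlation). The interferon gamma and dendritic cell maturation lists each had adjusted p = 0.00105 (adjusted p = 0.483 with an estimated correlation). Alternative activation had 0.00349 and metallothioneins 0.0011 (adjusted p = 0.593 with an estimated correlation for both). The macrophage-like cells of the 2 cultures lay in almost wholly different clusters. Clusters 0, 2, 3, 4, 6 and 8 each held at most 0.42% of them in a tri-culture, and clusters 1, 5, 9 and 16 at most 0.06% in a co-culture. Dendritic cells, 24 h more of culture and fewer wells cannot be told apart in this comparison.

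Over all 4 contexts, few single genes passed with bemcentinib in macrophage-like cells, and lysosomal genes had small positive changes, a list call that was lost with an estimated correlation (adjusted p = 0.167). All 33 genes of the lysosome and TFEB target list had a positive log2 change (median 0.35), none passed over all genes and 20 rose adjusted over the list alone. GPNMB had a log2 change of 1.13 ± 0.14 and CTSD of 0.78 ± 0.14. The rule named 1 gene, SLC47A1, an organic cation exporter, which rose from 33.7 to 62.1 CPM (0.89 ± 0.05). The other called genes, named after their values were seen, were PMEL (2.57 ± 0.20, 1.75 to 11.8 CPM), MLPH (1.33 ± 0.12), TSPAN10 (2.13 ± 0.19), BIRC7 (2.18 ± 0.17) and MMP3, which rose, and RUFY4 (-2.83 ± 0.25), which fell. MMP3 stood at no more than 0.0189 CPM with DMSO and at no more than 1.6 CPM with bemcentinib. PMEL, MLPH, TSPAN10 and BIRC7 are known from pigment cells and melanoma, but PMEL stood at no more than 1.56 CPM in melanoma-like cells of any library. DUSP6 (-1.11 ± 0.28), MERTK (-0.44 ± 0.11, 72.3 to 52.7 CPM) and AXL (-0.25 ± 0.37) did not pass.

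Thus 6 genes rose and 1 fell of 12854 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4 libraries against 4), against 616 called by DESeq2, and 1594 had an unadjusted p under 0.05 where 643 are given by chance. By camera the lysosome list had adjusted p = 2.58e-18, and adjusted p = 0.167 with an estimated correlation. The melanocyte list, in which PMEL rose, had 7.80e-05 by camera, and adjusted p = 0.167 with an estimated correlation. Fry, which does not set a list against other genes, gave adjusted p = 0.0154 for both. It gave 0.667 for the cholesterol list, 0.697 for type I interferon and 0.48 for MAPK output. Leaving out any 1 library gave 0 to 2 genes, at most 1 of them among the 7, and a term for the interaction of A375 state with culture, added after the data were seen, gave 133.

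Within each A375 state more genes passed, and the groups that moved were partly shared. Beside untreated A375, 494 genes rose and 328 fell with bemcentinib, and beside injured A375 1030 passed, of which 655 rose (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2 libraries against 2, comparisons added after the data were seen). Of these, 141 genes rose in both states where independent calls would give 25.2, and 33 fell in both where they would give 9.6. In opposite directions, 36 rose beside untreated and fell beside injured A375 (14.4 if independent), and 34 did the reverse (16.7 if independent). Both sets of calls came from 1 model of the same libraries and are not independent. The excess in either direction therefore does not measure a shared response. The lysosome list had 8 of 33 genes that rose beside untreated A375 (median 0.31) and 13 of 33 beside injured A375 (median 0.35), with no falls. GPNMB rose in both, from 1880 to 4480 CPM and from 3950 to 7940 CPM, CTSD by 0.79 ± 0.11 beside untreated A375, and NPC1, a lysosomal cholesterol transporter, by 0.86 ± 0.12 beside injured A375. HS3ST2, a heparan sulfotransferase, rose in both (2.52 ± 0.21 from 112 to 552 CPM and 1.88 ± 0.21 from 263 to 1010 CPM).

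Beside untreated A375, part of the type I interferon genes rose with bemcentinib in macrophage-like cells. Of 26 measured, 10 rose and none fell (24 rose adjusted over the list alone; median 0.99), such as MX1 (1.27 ± 0.22), IFI44L (1.38 ± 0.25) and OAS1 (1.01 ± 0.16). In the co-culture pair an interferon-led cluster went from 3.38% to 50.06% of these cells, and in the tri-culture pair the list's median was 0.14 in cells of 5000 to 10000 UMIs, against 0.44 in all cells. In the complement list 5 of 14 rose, such as C3 (0.80 ± 0.07). In the MAPK list 5 of 18 fell (8 adjusted over the list alone; median -0.58), and in the S phase list 5 of 20 fell (median -1.29); 14 of the MAPK and 18 of the S phase genes are more abundant in melanoma-like cells. By the rule, NUPR1, a stress-induced gene (1.55 ± 0.25, 191 to 619 CPM), and IL17RB (1.86 ± 0.09) rose. The lipid-antigen presenting molecule CD1B (-3.86 ± 0.43), the cyclin CCND2 (-2.59 ± 0.10) and lipoprotein lipase LPL (-1.80 ± 0.08, 436 to 130 CPM) fell. In the untreated tri-cultures, dendritic cell RNA was bounded at 5.33% with DMSO and 2.25% with bemcentinib, and a cycling cluster held 10.73% and 1.02% of macrophage-like cells. The median dendritic cell marker ratio was higher than these bounds, at 26.0% and 10.2%. The interferon list had camera adjusted p = 4.20e-09 (adjusted p = 0.827 with an estimated correlation), lysosomes 3.39e-11 and MAPK 5.11e-05 (adjusted p = 0.595 with an estimated correlation for both). S phase had 7.74e-08 and complement 0.00594 (adjusted p = 0.827 with an estimated correlation for both). The balance of rises and falls turned without the untreated co-culture with DMSO (73 rose and 127 fell) and without that with bemcentinib (80 rose and 138 fell), and 109 and 121 of the 822 genes remained called. In simulated counts of this comparison, 26 wrong calls came with 92 right ones for 1.5-fold changes.

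Beside injured A375, cholesterol and stress response genes rose with bemcentinib. In the cholesterol list 8 of 23 rose and none fell (14 rose adjusted over the list alone; median 0.45). In the integrated stress response list, of whose members 8 are more abundant in melanoma-like cells, 6 of 16 rose (median 0.58), among them its transcription factor ATF4 (0.52 ± 0.07), and in the unfolded protein response list 5 of 14 rose, among them XBP1 (0.54 ± 0.06). By the rule, PMEL (2.83 ± 0.14, 2.92 to 21 CPM) and the scavenger receptor MARCO (2.16 ± 0.08, 9.63 to 42.3 CPM) rose. PDK4, a regulator of glucose oxidation (-2.46 ± 0.29), the lectin CLEC10A (-1.50 ± 0.09, 134 to 45.9 CPM) and the chemokine CCL5 (-1.33 ± 0.13, 889 to 379 CPM) fell. AXL fell from 28.7 to 15.7 CPM (-0.97 ± 0.15) and is more abundant in melanoma-like cells. The lysosome, cholesterol, stress response and unfolded protein response lists had camera adjusted p = 1.15e-08, 2.94e-07, 6.20e-04 and 7.65e-04, and each had adjusted p = 0.611 with an estimated correlation. No gene of the type I interferon list passed (median -0.33, camera adjusted p = 0.0163, and adjusted p = 0.827 with an estimated correlation). Leaving out 1 injured library left 0 or 1 called genes.

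Whether the change with bemcentinib differed between A375 states, or between cultures, was tested as an interaction. No gene passed for A375 state by edgeR (smallest adjusted p = 0.205 by its quasi-likelihood test with Benjamini-Hochberg adjustment), with 1962 at an unadjusted p under 0.05 and 684 called by DESeq2. With a term for A375 state by culture, added after the data were seen, 215 genes had a higher and 191 a lower change beside injured A375. The list tests of both interactions were not planned. Among lists, the interferon list had a median interaction of -1.20 (camera adjusted p = 3.85e-07), cholesterol 0.61 and complement -0.53 (both 1.75e-06), and the integrated stress response 0.47 (0.0282), each with adjusted p = 0.632 with an estimated correlation. No gene passed for culture by edgeR either (smallest adjusted p = 1 by its quasi-likelihood test with Benjamini-Hochberg adjustment), with 112 at an unadjusted p under 0.05 and 1 called by DESeq2. The NF-kB list had a median interaction with culture of 0.49 (camera adjusted p = 2.26e-09), and adjusted p = 0.172 with an estimated correlation. The G2 and M phase list had -1.67 (1.56e-11), and adjusted p = 0.983 with an estimated correlation.

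In the 4 contexts taken singly, each 1 bemcentinib library against 1 DMSO library with no replicate check, the interferon list separated by A375 state. Its median log2 ratio was 1.35 (bootstrap interval 1.21 to 1.87) in untreated co-culture and 0.51 (0.42 to 0.63) in untreated tri-culture, above all 10000 random lists of like expression. In cells of 5000 to 10000 UMIs the untreated tri-culture value was 0.14, against 0.44 in all cells computed the same way. The list's median was -0.34 (-0.41 to -0.23) in injured co-culture and -0.33 (-0.49 to -0.20) in injured tri-culture, below all the random lists. Random lists hold genes drawn one by one, so these percentiles ignore the correlation among interferon genes. In the other classes the medians were of like sign. Those of melanoma-like cells, in which every gene of the list had a lower mean CPM over the 8 libraries than in macrophage-like cells, were 1.07 and 0.41 beside untreated A375 and -0.16 and -0.11 beside injured A375. The last pair stood at percentiles 1.9 and 6.17 of the random lists. Those of dendritic-cell-like cells were 1.80 and -0.16. In macrophage-like cells IFIT1 went from 133 to 728 CPM in untreated co-culture and from 360 to 248 CPM in injured co-culture. The lysosome list had medians of 0.32, 0.26, 0.35 and 0.38 in untreated co-culture, injured co-culture, untreated tri-culture and injured tri-culture, and GPNMB went from 1830 to 4320, 4620 to 8400, 1930 to 4640 and 3280 to 7490 CPM. In the same order the cholesterol list had 0.01, 0.19, -0.29 and 0.60, and the metallothioneins 0.29, -0.70, -0.05 and -1.64. Across genes, which are not independent replicates, the ratios of macrophage-like cells had a Pearson r of 0.47 between the untreated contexts and 0.51 between the injured ones, and of 0.10 to 0.18 between contexts of different A375 state.

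In co-culture, macrophage-like cells with DMSO and with bemcentinib also fell into different clusters. Cluster 6, led by interferon-induced genes such as CXCL10, IFIT1 and MX1, held 3.38% of them with DMSO and 50.06% with bemcentinib beside untreated A375, and cluster 4 held 52.54% and 12.65%. Beside injured A375, cluster 8 held 38.11% and 4.1%, and cluster 0 held 17.06% and 67.33%. The drug comparisons in co-culture thus set cells of partly different clusters against each other.

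**Figure D3:**
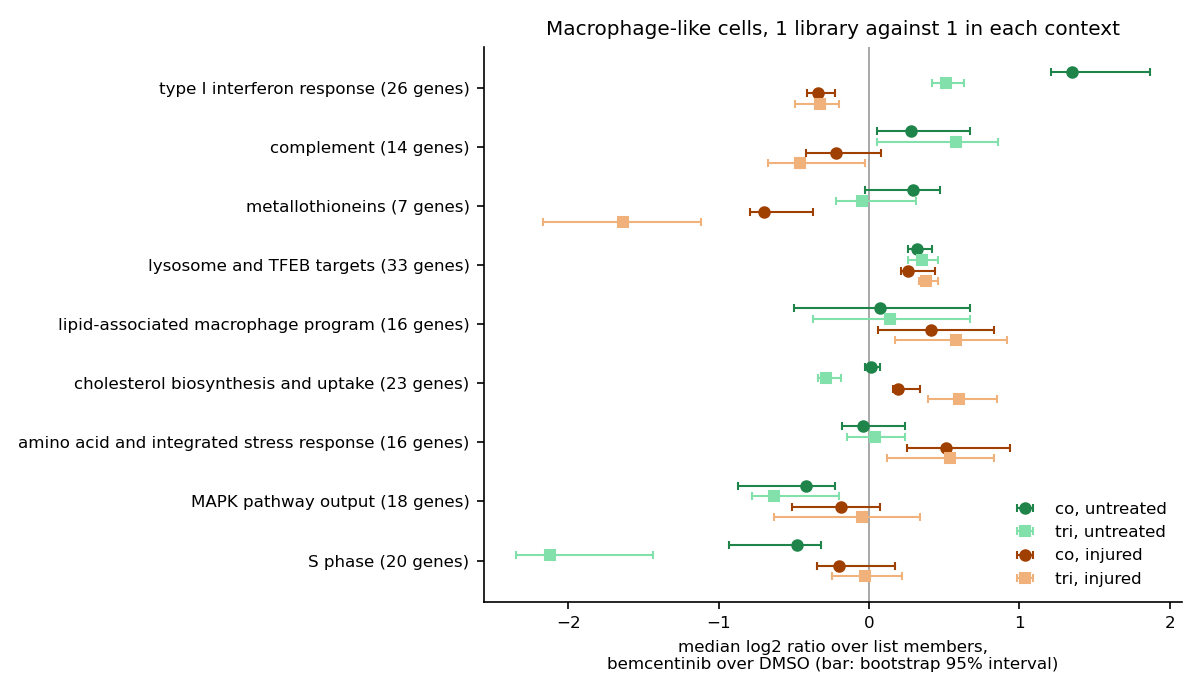
Median log2 ratio of bemcentinib over DMSO (x axis, bootstrap interval) of gene lists in macrophage-like cells in each of the 4 contexts, 1 library against 1. The interferon list lies at 1.35 and 0.51 beside untreated A375, the latter 0.14 in cells of 5000 to 10000 UMIs, and at -0.34 and -0.33 beside injured A375.

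**Figure D4:**
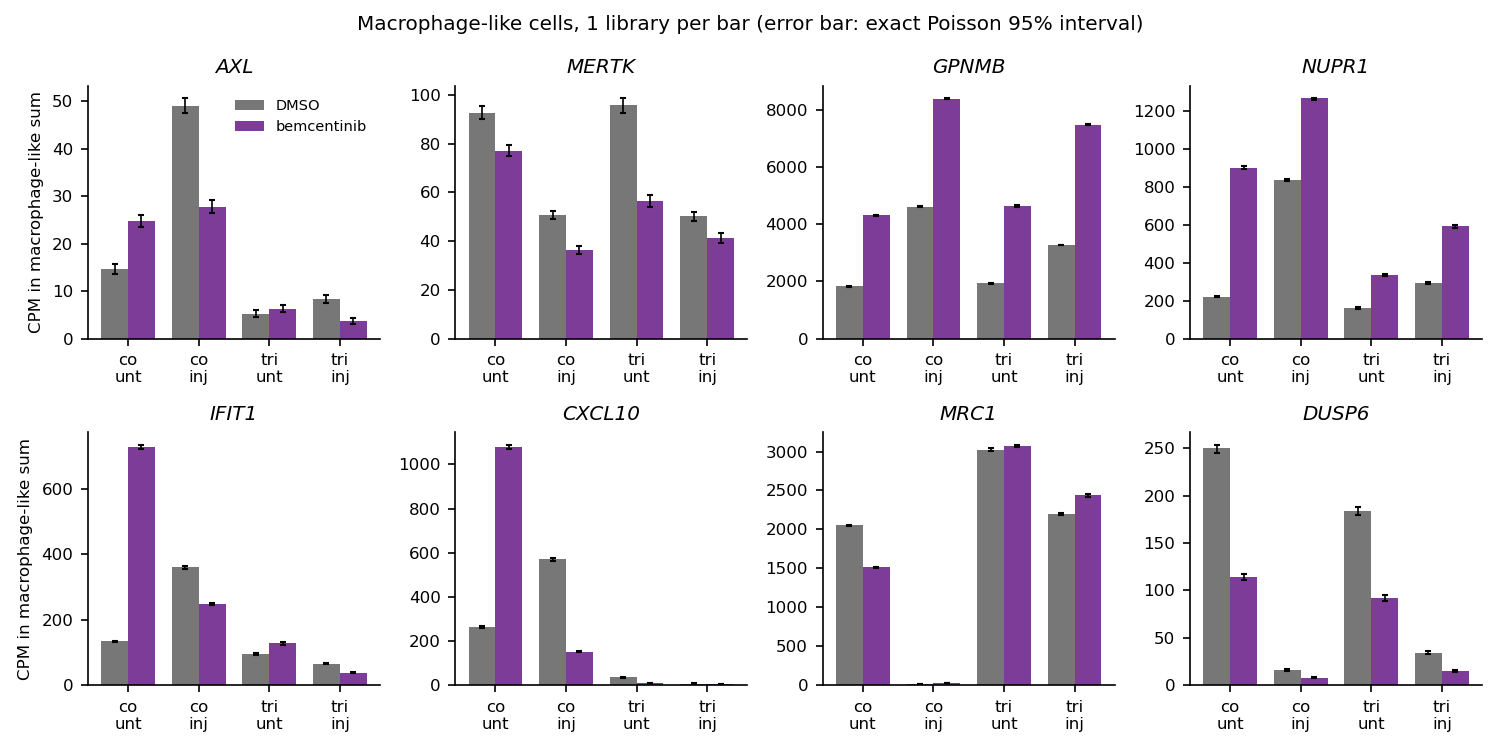
Level of 8 genes in the summed counts of macrophage-like cells, in CPM (y axis), as 1 bar per library grouped by context (co or tri, untreated or injured) with exact 95% Poisson intervals of counting. GPNMB was higher with bemcentinib in each of the 4 contexts, from 1830 to 4320 CPM in untreated co-culture.

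In dendritic-cell-like cells of the tri-cultures, bemcentinib went with higher lysosomal genes and lower MAPK output and MERTK. In the lysosome list 3 of 33 rose and none fell (14 rose adjusted over the list alone; median 0.27), among them GPNMB and the hexosaminidase subunit HEXA (0.56 ± 0.08). In the MAPK list 5 of 15 fell (10 adjusted over the list alone), among them ETV5 (-0.64 ± 0.11), and 12 of the 15 are more abundant in melanoma-like cells. The S phase list had 5 of 20 that fell (15 adjusted over the list alone; median -1.49), and 18 of them are more abundant in melanoma-like cells. Of 26 genes of the type I interferon list none passed (median 0.73). MERTK fell from 20.3 to 11.8 CPM (-0.76 ± 0.13). By the rule, NUPR1 (1.71 ± 0.09, 18.7 to 61.7 CPM) and the purinergic receptor P2RY13 (1.42 ± 0.09) rose, and IDO1 (-1.98 ± 0.15, 27.2 to 6.52 CPM) and the inhibitory receptor SIGLEC10 (-1.28 ± 0.09) fell. In macrophage-like cells of the tri-cultures MERTK went from 95.7 to 56.4 CPM beside untreated and from 50.1 to 41.2 CPM beside injured A375. NUPR1 went there from 162 to 337 and from 293 to 593 CPM, while IDO1 stood at no more than 0.344 CPM. Macrophage RNA among the dendritic-cell-like counts was not bounded, so its part in these changes was not tested. Cluster 26, led by LAMP3, CCR7 and CCL22, held 1.9% of these cells with DMSO and 1.49% with bemcentinib beside untreated A375, and 6.9% and 2.02% beside injured A375, so the make-up of the class differed too. Cluster 17, also of this class, had 12 dendritic cell and 11 macrophage markers above the rest. In all, 174 genes rose and 136 fell of 12044 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2 libraries against 2 and 1 residual degree of freedom), and without cluster 17, a setting chosen after the data were seen, 176 were called. In simulated counts of this comparison, 38 wrong calls came with 182 right ones for 2-fold changes. Camera gave adjusted p = 2.24e-11 for lysosomes, 8.15e-06 for MAPK and 1.05e-04 for interferon, and adjusted p = 0.973 with an estimated correlation for each. Fry gave adjusted p = 0.183 for lysosomes and for MAPK, and 0.855 for interferon.

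Beside injured A375, dendritic-cell-like cells had lower cholesterol, MAPK and inflammatory genes. In the cholesterol list 13 of 23 fell and none rose (15 adjusted over the list alone; median -0.43), such as HMGCS1 (-0.53 ± 0.07). In the MAPK list 7 of 15 fell (12 fell and 1 rose adjusted over the list alone), such as ETV5 (-1.22 ± 0.11) and MYC (-0.78 ± 0.08), and 12 of the 15 are more abundant in melanoma-like cells. ETV4 had no counts beside injured A375 and was at least 9.76-fold lower against a floor of 3 counts over the group. In macrophage-like cells A375 RNA could give at most 71.0% of the fall of ETV4. RNA of A375 or of macrophage-like cells among the dendritic-cell-like counts was not bounded, so the fall of ETV4 may be that of carried-over RNA. In the NF-kB list 7 of 22 fell and 1 rose, such as TNF (-1.13 ± 0.14) and CCL2 (-1.13 ± 0.09). By the rule, IDO1 rose (3.58 ± 0.15, 2.5 to 31.2 CPM), as did the iron exporter SLC40A1 (1.52, 63.6 to 187 CPM), and the protease MMP12 (-1.78 ± 0.11, 211 to 60.5 CPM), FOS (-1.69 ± 0.14) and the LPS co-receptor CD14 (-1.61 ± 0.08, 281 to 92.3 CPM) fell. In all, 231 genes rose and 284 fell of 12044 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2 libraries against 2 and 1 residual degree of freedom). DESeq2 called 179 that rose and 193 that fell. Without cluster 17, a setting chosen after the data were seen, 165 of the 515 genes were called. That cluster held 23.08% and 26.26% of these cells beside untreated A375 with DMSO and bemcentinib, and 13.51% and 21.02% beside injured A375. It had 12 dendritic cell and 11 macrophage markers above the rest, so its name is uncertain. Like CD14, the macrophage markers CD163, VSIG4, FOLR2 and MS4A4A fell. Whether these falls follow the share of cluster 17 rather than a change within dendritic cells was not tested. Camera gave adjusted p = 3.92e-08 for cholesterol, 9.20e-07 for MAPK and 1.95e-04 for NF-kB, and adjusted p = 0.801 with an estimated correlation for each.

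In melanoma-like cells, bemcentinib went with higher lysosomal and stress response genes. In the lysosome list 5 of 33 rose and none fell (17 rose adjusted over the list alone; median 0.24). SQSTM1, an autophagy receptor, rose from 1290 to 2620 CPM (1.07 ± 0.14), and FLCN (0.99 ± 0.12) and FNIP1 (0.54 ± 0.07), partners in the control of TFEB, rose too. MCOLN3, an endolysosomal channel (0.89 ± 0.11), and RRAGC, a GTPase of lysosomal nutrient sensing (0.80 ± 0.08), were among the largest rises by the rule. In the integrated stress response list 4 of 16 rose and none fell (13 rose adjusted over the list alone; median 0.52), such as SLC3A2, an amino acid transporter subunit (0.66 ± 0.08), and GDF15, a stress-induced cytokine named by the rule, rose by 1.08 ± 0.12. Among the genes named by the rule, the collagen COL5A3 (-1.12 ± 0.13, 337 to 143 CPM), tenascin TNC (-0.72 ± 0.10, 1070 to 628 CPM) and the laminin subunit LAMA4 (-0.58 ± 0.05) fell; the dedifferentiation and mesenchymal list, which holds TNC, had 1 of 18 that fell (8 adjusted over the list alone; median -0.38). SPRY2 fell from 362 to 263 CPM (-0.48 ± 0.07), and was 1 of 19 MAPK genes that did (median -0.27). AXL (-0.43 ± 0.10, 187 to 145 CPM) and DUSP6 (-0.31) did not pass. Of 20 S phase and 20 G2 and M phase genes none passed, and all had a negative change (medians -0.42 and -0.57). By camera these lists had adjusted p = 2.79e-05 and 0.011, and adjusted p = 0.508 and 0.604 with an estimated correlation. In co-culture and tri-culture the G2 and M phase median was -0.11 and 0.12 beside untreated A375, and -0.85 and -1.51 beside injured A375.

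In all, 37 genes rose and 22 fell of 13594 in melanoma-like cells with bemcentinib (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4 libraries against 4), against 442 called by DESeq2. The lysosome list had camera adjusted p = 6.94e-16, and adjusted p = 0.0217 with an estimated correlation. Most of its members (25 of 33) are more abundant in macrophage-like cells. The stress response, dedifferentiation and MAPK lists had 8.08e-12, 9.79e-08 and 8.10e-04, each with adjusted p = 0.135 with an estimated correlation. Fry gave adjusted p = 0.00127 for lysosomes, 0.0221 for the stress response, 0.0236 for dedifferentiation and 0.0149 for MAPK. For the S phase and the G2 and M phase lists it gave 0.313 and 0.496. Leaving out 1 library gave 0 to 32 genes, at most 19 of them among the 59, no covariates gave 0, and the added term for A375 state by culture gave 661.

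Between cultures, melanoma-like cells of the tri-cultures had lower NF-kB and stress response genes than those of the co-cultures. In the NF-kB list 10 of 21 fell and none rose (14 fell adjusted over the list alone; median -1.24), such as PTGS2, the inducible cyclooxygenase (-3.47 ± 0.24), and IL1A (-1.53 ± 0.27), and 15 of the 21 are more abundant in macrophage-like cells. In the stress response list 8 of 16 fell (11 adjusted over the list alone; median -0.43), such as DDIT3 (-1.31 ± 0.13). In the G2 and M phase list 2 of 20 rose, CCNB1 (1.65 ± 0.37) and AURKA (1.14 ± 0.27), with 12 adjusted over the list alone (median 1.21). Cluster 12, led by cell cycle genes such as CDK1 and MKI67, held 47.46% and 35.13% of melanoma-like cells in the untreated co-cultures with DMSO and bemcentinib and 32.12% and 34.4% in the untreated tri-cultures. Cluster 32, with TOP2A and PLK1 among its leading genes, held 1.96% and 0.39% in the injured co-cultures and 11.89% and 3.43% in the injured tri-cultures. By the rule, the cytokine IL32 (-3.19 ± 0.11, 236 to 27.3 CPM), the receptor EGFR (-1.71 ± 0.13, 38.8 to 11.6 CPM) and TRAF1 (-1.58 ± 0.21) fell, and IGFBP5 (2.02 ± 0.43) and the complement regulator CFI (1.06 ± 0.10) rose. In the alternative activation list 9 of 18 rose and 1 fell, and 15 of the 18 are more abundant in macrophage-like cells. In all, 604 genes rose and 540 fell of 13594 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4 libraries against 4). Camera gave adjusted p = 1.30e-07 for NF-kB, 3.99e-06 for the stress response and 1.26e-06 for G2 and M phase. They had adjusted p = 0.0846, 0.251 and 0.444 with an estimated correlation. Without covariates 2 genes were called, leaving out 1 library gave 307 to 707, and the added term for A375 state by culture gave 2868.

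AXL and its relative TYRO3 were higher in melanoma-like cells, and MERTK was higher in macrophage-like cells. AXL (chromosome 19, 41219203 to 41261766, plus strand, GRCh38) stood at 284 and 237 CPM in melanoma-like cells of the untreated co-cultures with DMSO and bemcentinib, and at 104 and 76.6 CPM in the injured ones. In macrophage-like cells of the same libraries it stood at 14.6, 24.8, 49.1 and 27.7 CPM, and in the tri-cultures at no more than 8.33 CPM. MERTK (chromosome 2, 111898479 to 112029561, plus strand) stood at 92.6 and 77 CPM in macrophage-like cells of the untreated co-cultures with DMSO and bemcentinib and at 50.8 and 36.3 CPM in the injured ones. TYRO3 (chromosome 15, 41557675 to 41583586, plus strand) stood at 34.4 to 91.1 CPM in melanoma-like cells and at 0.345 to 2.96 CPM in macrophage-like cells over the 8 libraries.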

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

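The tests of carried-over A375 RNA and of debris, the division of the depth test of interferon genes by context, the test of the interaction of A375 state with culture, and the term for it in the test of bemcentinib by A375 state, were chosen after the results were seen.

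In macrophage-like cells the change with A375 state differed between the cultures for 136 genes, by edgeR's quasi-likelihood test of the interaction with Benjamini-Hochberg adjustment. For 114 of them the change with injury was higher in tri-culture, and for 22 it was lower. Without either injured co-culture 0 genes were called, and without any other library 19 to 88. MRC1, the mannose receptor and 1 of the fixed macrophage markers, stood at 2050 and 1510 CPM in the untreated co-cultures with DMSO and bemcentinib and at 18.2 and 22.7 CPM in the injured ones. In the tri-cultures it stood at 3020 and 3070 CPM beside untreated and at 2200 and 2440 CPM beside injured A375 (log2 interaction 6.06 ± 0.31, adjusted p = 0.00749). The low-affinity IgE receptor FCER2, a fixed dendritic cell marker (6.43), the glutamyl transferase GGT5 (6.79), STEAP4 (6.20), STAC (6.01) and APOL4 (5.98) had the same form. GGT5 stood at 76.7 and 87 CPM in the untreated co-cultures and at 0.485 and 1.02 CPM in the injured ones, against 75.7 to 153 CPM in the tri-cultures. The interactions furthest below 0 by the rule were those of CHST2 (-2.95), AP1S3 (-2.30), APOO (-1.73), the membrane linker RDX (-1.70), MSC (-1.64) and TOM1L2 (-1.42). CHST2 stood at 39 and 44.8 CPM in the untreated and at 194 and 174 CPM in the injured co-cultures, and at no more than 5.74 CPM in the tri-cultures. In the MAPK list 3 of 18 genes had a higher and 1 a lower interaction, and in the alternative activation list 2 of 18 had a higher one.

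The tests argue against depth as the source of the 114 genes held up beside injured A375 in tri-culture. They also argue against RNA like that of the average dendritic-cell-like cell. In cells of 5000 to 10000 UMIs their median interaction was 2.2, against 2.17 in all cells. RNA of dendritic-cell-like cells could give at most 1.17% of the level of the median gene in the injured tri-cultures. That bound rests on the fixed marker with the lowest ratio, CD1A with DMSO and FCER1A with bemcentinib. The median marker ratio was 4.14% and 4.51%. Dendritic cells low in these markers, if placed among the macrophage-like cells, are not excluded. Whether the longer culture or the added dendritic cells went with the difference cannot be told apart, since 0 libraries separate them. A loss of these transcripts beside injured A375 that later recovers, or that dendritic cells offset, may be at work, and stays a hypothesis.

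MAPK output genes were lower in macrophage-like cells beside injured A375, although the inhibitors are listed only as a treatment of the A375 cells. The median change was -2.34 in cells of 5000 to 10000 UMIs and -2.28 without the cycling cluster, against -2.26 in all cells, which argues against depth and cycling cells. Carried-over A375 RNA could give at most 2.63% of the fall of the median member, and under 0.5 of it for 12 of 17 members, which argues against it as the whole source. Inhibitor carried along with the A375 cells could act on the macrophages directly, and a change in growth factors made by A375 could do so too. Neither was tested, and no condition of the design separates them.

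Type I interferon genes had medians above 0 with bemcentinib beside untreated A375 (1.35 in co-culture and 0.51 in tri-culture) and below 0 beside injured A375 (-0.34 and -0.33), each 1 library against 1. This difference between A375 states was not tested in the single contexts. Depth is argued against in untreated co-culture, injured co-culture and injured tri-culture, where cells of 5000 to 10000 UMIs kept at least 84.2% of the median, but in untreated tri-culture they kept 32.2%, so that depth may account for much of that value. The list was lower in the library with more barcodes of 100 to under 1000 UMIs in 3 of 4 pairs, so debris in the library cannot be told apart from the drug. A drug effect that depends on A375 state stays open, since the planned test of this interaction called 0 genes (smallest adjusted p = 0.205) and a term for A375 state by culture, added after the data were seen, gave 406.

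An unnamed cluster of 406 cells, led by CCL19, EBI3, IDO1, CCR7 and LAMP3, lay outside the compared classes, with 170 cells (1.497%) and 230 cells (1.99%) in the injured co-cultures with DMSO and bemcentinib and at most 4 in any other library. A second unnamed cluster of 44 cells was led by IGHM, IGKC, JCHAIN, MS4A1 and CD79B, genes of B cells and plasma cells. Clusters of low UMI count held 33.74% of the kept cells in the untreated tri-culture with DMSO and 24.27% in that with bemcentinib, and took no part in the comparisons.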

How the results depend on the processing

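The terms for A375 state by culture and by drug, the removal of single clusters and all settings of the 3 added comparisons were chosen after the data were seen. No paired analysis was possible by replicate number or donor, because the numbers are all 1 and pair no samples. Libraries were matched on the other factors instead, by terms of the models, by the rule for named genes and in the exact permutation of shares over matched pairs. Counts are genes past an adjusted p of 0.05, and the cause was not tested for any change below except where fewer libraries were fitted. For bemcentinib in macrophage-like cells (7 genes), DESeq2's size factors gave 11, no filter on low counts 17, DESeq2's Wald test 616, at least 1000 genes per cell 11, doublets kept 18, no covariates 0, all myeloid cells 0, removal of the cycling cluster 15 and the added term 133. For A375 state in macrophage-like cells (1267) the Wald test gave 3122, no covariates 22 and the added term 2775, and for culture (4494) no covariates gave 2604. For bemcentinib in melanoma-like cells (59), no filter gave 94, the Wald test 442, doublets kept 13, no covariates 0 and the added term 661, and for culture (1144) no covariates gave 2 and the added term 2868. For bemcentinib by A375 state (0 by edgeR, 1962 at an unadjusted p under 0.05) the Wald test gave 684 and the added term 406, and for bemcentinib by culture (0 by edgeR, 112 at an unadjusted p under 0.05) the Wald test gave 1. Without dendritic cluster 17, the counts for dendritic-cell-like cells were 176 for bemcentinib (310) and 165 for A375 state (515). For A375 state by culture (136) the Wald test gave 794, all myeloid cells 250 and a term for A375 state by drug 946. For bemcentinib beside untreated A375 (822) the Wald test gave 1308 and all myeloid cells 468, and beside injured A375 (1030) all myeloid cells gave 402. With an estimated correlation 1 gene list, the lysosome list, was called for bemcentinib in melanoma-like cells and 0 in each other comparison. In simulated counts of bemcentinib beside untreated A375 and in dendritic-cell-like cells, a moved list was not called with an estimated correlation at any fold. For bemcentinib by A375 state it was called only at a fold of 4, where the log2 interaction was 2 times the log2 of that fold. In the remaining simulated comparisons it was called at each fold. Where the moved list was missed, a lost list call says little. Elsewhere the simulations do not decide what a lost call means, since their genes were drawn one by one without correlation. With bemcentinib in macrophage-like cells, the estimated correlation was 0.898 for the interferon list and 0.141 for the lysosome list.

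Leaving out each library in turn fits fewer libraries. Counts below follow the order co-culture then tri-culture, untreated then injured A375 in each, and DMSO then bemcentinib in each of those. For bemcentinib in macrophage-like cells the counts ran from 0 to 2, with at most 1 of these genes among the 7, so each library moves that result. For A375 state in macrophage-like cells they ran from 41 to 1546: 203, 41, 49 and 50 without a co-culture, 252 and 174 without the untreated and the injured tri-culture with DMSO, and within 1.5 times of the full count without either tri-culture with bemcentinib. For culture in macrophage-like cells they ran from 2724 to 3714, and were 2950 without the untreated co-culture with bemcentinib, 2781 and 2925 without the injured co-cultures and 2724 and 2960 without the injured tri-cultures. For A375 state in melanoma-like cells they ran from 7166 to 7950, all within 1.5 times. For culture in melanoma-like cells they were 307, 355, 428, 607, 346, 388, 707 and 462, and for bemcentinib 0, 0, 0, 4, 17, 0, 32 and 8, of which 3, 14, 19 and 5 in the nonzero fits were among the 59. For A375 state by culture they were 19, 33, 0, 0, 25, 88, 29 and 28, and for both interactions of bemcentinib 0 throughout. For bemcentinib beside untreated A375 they were 200, 218, 405, 427, 252, 236, 285 and 319, with more falls than rises in the first and the second (73 against 127, and 80 against 138). Beside injured A375 they were 0 to 1040, with 0 without either injured co-culture and 1 without either injured tri-culture. In the comparisons of dendritic-cell-like cells, leaving out a library leaves no residual degrees of freedom, so no test was run. For the named genes 2969 values over 205 genes were recomputed: 2360 kept their direction and side of the threshold, 609 kept the direction alone and 0 reversed. All 16 shares moved by less than their spread, and 97 of 104 list medians in single contexts did so without TMM factors. The smallest sum came from 488 melanoma-like cells, and in simulated counts 0.5% of 1.5-fold changes with bemcentinib in macrophage-like cells were recovered, so changes of that size were mostly not detectable.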

Other observations

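The comparisons of other groupings of the libraries were planned for the 8 comparisons of macrophage-like and melanoma-like cells fixed beforehand, and the one for A375 state by culture was chosen after the result was seen.

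Macrophage-like cells of the tri-cultures were spread over clusters that differed by A375 state in part. Cluster 5 held 47.62% and 48.24% of them beside untreated A375 with DMSO and bemcentinib, and 18.6% and 2.52% beside injured A375. Cluster 1 held 2.8% and 10.65% beside untreated and 50.16% and 60.22% beside injured A375. Cluster 18 held cells of all 8 libraries, from 1.65% to 13.34%. A cycling cluster held 10.73% of the macrophage-like cells in the untreated tri-culture with DMSO, 1.02% in that with bemcentinib, 1.78% and 0.76% in the untreated co-cultures, and no more than 0.11% beside injured A375. NUPR1, a stress-induced gene, stood in macrophage-like cells at 221 and 901 CPM in untreated co-culture with DMSO and bemcentinib, at 838 and 1270 CPM in injured co-culture, at 162 and 337 CPM in untreated tri-culture and at 293 and 593 CPM in injured tri-culture. The lipid-associated macrophage list, which holds GPNMB, TREM2 and PLIN2, had medians with bemcentinib of 0.07 and 0.14 beside untreated A375 in co-culture and tri-culture, and of 0.41 and 0.58 beside injured A375. Each of these is 1 library against 1.

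CXCL10, an interferon-induced chemokine, stood in macrophage-like cells at 262 CPM with DMSO and 1080 CPM with bemcentinib in untreated co-culture, and at 569 and 151 CPM in injured co-culture. In the tri-cultures it stood at no more than 34.7 CPM. IDO1 stood at 334 and 165 CPM in the injured co-cultures and at no more than 8.25 CPM elsewhere. In melanoma-like cells, the changes with bemcentinib had a Pearson r across genes of 0.42 between the untreated contexts and 0.40 between the injured ones, and of 0.15 to 0.31 otherwise. In dendritic-cell-like cells it was 0.39. Genes are not independent replicates.

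Other splits of the 8 libraries into 4 against 4 were fitted with the same covariates. For A375 state in macrophage-like cells 1 of 33 splits, the real one, gave as many genes (1267, highest other 0), for culture in macrophage-like cells 1 of 33 (4494, highest other 0), for A375 state in melanoma-like cells 1 of 33 (8475, highest other 0), and for culture in melanoma-like cells 1 of 33 (1144, highest other 2). In each other split the real factor was left out of the model and so lay in its residual, which can lower the other counts. The splits therefore do not exclude chance for these comparisons. Nor do they exclude it for bemcentinib in macrophage-like cells, where 3 of 33 splits gave at least the real 7 genes. The highest other, 49, followed the combination of culture and A375 state, a structure of the libraries. Chance is also not excluded for bemcentinib in melanoma-like cells, where 2 of 33 gave at least the real 59. There another split gave 227, several times as many, which points to structure that the additive model leaves out. For bemcentinib by A375 state and bemcentinib by culture the real count was 0, which all 32 splits reach by construction, so the splits decide nothing. The highest other, 136, was the split along A375 state by culture. For that interaction 1 of 32 splits gave as many as the real 136 (highest other 50). Since it was chosen after the data were seen, and without either injured co-culture 0 genes passed, this count does not exclude chance.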
